A study of Mus musculus with 6 samples.

How the data were processed

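Liver RNA of male mice on a high-fat diet was sequenced in 6 libraries, 3 labelled WT and 3 labelled Trem2-deficient. Per the labels' protocols, RNA was extracted with Trizol from frozen liver and libraries were made from 1 ug of total RNA with an Illumina TruSeq kit; whether strand was kept is not given in the sources used here. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the mouse genome build mm10, without their roles or settings. Groups were taken from the sample titles, which give each library its own replicate number, so that no pairing of libraries across groups was used. As a check for 1 library deposited under 2 names, the counts of each pair were compared; the lowest chi-square per degree of freedom was 47.4, far above sampling noise. The labels do not say that each library came from another mouse; if some did not, p-values measure only the spread between these samples.

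The authors' deposited count table holds whole read counts per gene for 54532 genes, with gene names, positions, lengths and types. The authors' deposited FPKM table holds the same genes and was used only as an alternative. In it, count divided by length and FPKM gave 1 library size per sample, equal to the DESeq2 size factor times the geometric mean of the column totals (ratio 1 in each library), rather than the column total itself. There, 27 gene names had been turned into dates, so names were taken from the count table. Because FPKM values are scaled in this way and low genes sit near 0, a log2 change of FPKM plus a constant understates the change of low genes.

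Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, genes kept by filterByExpr (13693 genes), a quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, without a fold minimum. The spread between libraries of a group was a biological coefficient of variation of 34.7%. SEs were taken as the log2 fold change over the square root of F. Exact permutation tests were two-sided. Poisson intervals of single counts are exact 95% intervals; they cover counting error only. Totals lay between 11591021 and 20399361 counts per library, and a gene at 1 CPM rests on few enough reads for counting error to matter, as for Trem2.

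Each of the 40 gene lists (liver cell types, lipid, mitochondrial, inflammatory and hepatocyte pathways, sex-biased genes, other tissues) was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 40 lists. Camera with an estimated correlation and fry were run beside it. The named genes were set by rule: Trem2; up to 12 called protein-coding genes per direction with groups that do not overlap and a mean of at least 1 CPM; and of each list the called members, up to 4, or otherwise the 2 with the smallest p. Some of the genes this rule takes are not reported here. Design, lists, naming rule and most alternatives were chosen before the data were examined. Genes within 10 Mb of Trem2 were compared with all others by Fisher's exact test.

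The tests were checked on simulated counts for the same 13693 genes, library sizes and group sizes. Of 50 genes changed per fold size, 3 were recovered at 2-fold, 28 at 4-fold, 43 at 8-fold and 43 at 16-fold, and 4 of 121 calls were false. A list of 25 genes raised 1.5-fold had an adjusted p of 0.000107, and 0 of 40 unchanged lists were called; simulated genes vary independently, unlike real ones.

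The alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scalings (DESeq2-type size factors, upper quartile, library size alone, and TMM without mitochondrial and the 10 most abundant genes), other filters, FPKM with pseudocounts of 1 and 0.1 in limma, a 1.5-fold minimum, other thresholds, and each library left out in turn. Added after seeing the data were 1 surrogate variable (sva 3.50.0), the log2 mitochondrial share as a covariate, robust dispersions, and WT replicate 1 and KO replicate 4 left out together. GC content was taken from GENCODE vM21 transcripts, whose gene positions match the count table for Trem2.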

Results

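Bulk RNA sequencing gave 6 liver libraries from male littermate mice, 3 labelled wild type (WT) and 3 labelled Trem2-deficient (KO). A high-fat diet, a model of fatty liver disease, was begun at 8 weeks of age and lasted 8 weeks. The libraries held 18337379, 13866345 and 20399361 counts for WT replicates 1, 2 and 3, and 11591021, 19653758 and 15915618 for KO replicates 4, 5 and 6. The single comparison asks how liver gene expression on this diet differs where Trem2, a lipid-sensing receptor of macrophages, is missing. Values are CPM, counts scaled to a common library total, as mean ± SD of the 3 libraries of a group, and changes are log2 fold changes of KO-labelled over WT-labelled libraries with their standard error (SE).

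Trem2 was scarce in whole liver and did not differ significantly between the labelled groups. The gene (ENSMUSG00000023992, mm10 chromosome 17, 48346401 to 48354147) had 7, 26 and 26 counts in the libraries labelled WT replicates 1, 2 and 3, and 9, 6 and 5 counts in those labelled KO replicates 4, 5 and 6. Its mean was 1.12 ± 0.627 CPM (SD, n = 3) in the WT-labelled and 0.475 ± 0.298 CPM (SD, n = 3) in the KO-labelled libraries. The fitted log2 fold change was −1.30 (SE 0.68), with an adjusted p of 0.633 in edgeR's quasi-likelihood test and p = 0.2 in a two-sided exact permutation test, whose smallest possible p is 0.1. The library labelled WT replicate 1, at 0.436 CPM (95% exact Poisson interval 0.175 to 0.899), lay inside the range of the KO-labelled libraries, 0.278 to 0.817 CPM. Trem2 therefore did not separate the labels, and each direction given here is between libraries as labelled. Which exons were deleted is not given in the sources used here, and counts from exons left in place would remain.

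Cyp2b9 and Ly6d were higher in all 3 KO-labelled livers, and no gene passed the threshold as lower. Cyp2b9 (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661), a steroid- and drug-metabolising cytochrome P450 that is female-predominant in mouse liver, went from 5.57 ± 1.09 to 113 ± 44.6 CPM (SD, n = 3 each). That is a 20.3-fold difference (log2 4.34, SE 0.37, edgeR adjusted p = 0.0298). Ly6d (ENSMUSG00000034634, chromosome 15, 74762056 to 74763620), a surface protein of the lymphocyte antigen 6 family, went from 0.506 ± 0.129 to 7.77 ± 1.13 CPM, a 15-fold difference (log2 3.91, SE 0.35, edgeR adjusted p = 0.0298). Reads of Cyp2b9 can also match its close relatives, among them Cyp2b13, so its level carries that uncertainty.

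These were the 2 genes past an adjusted p of 0.05 among 13693 tested with edgeR. At an unadjusted p under 0.05 there were 735 higher and 440 lower genes, where 685 in all would be expected by chance. The count of 1175 changed to 904, 2012 and 730 without WT replicate 1, 2 or 3, and to 623, 2662 and 776 without KO replicate 4, 5 or 6. These fits hold fewer libraries, so a lower count can also come from lost power, and they test other numbers of genes. The size of any excess over chance thus varied with the library left out. DESeq2 called 105 higher and 60 lower genes, limma-voom 1 and 0, and limma-voom with sample quality weights 2070 and 1993. In 13.9% of the tested genes the 3 KO-labelled values lay all above or all below the WT-labelled ones, where chance gives 10%. Leaving out WT replicate 1, 2 or 3 or KO replicate 4 or 6 ended both calls, with edgeR adjusted p between 0.0578 and 0.265 for Cyp2b9 and between 0.068 and 0.265 for Ly6d. Without KO replicate 5, Cyp2b9 had an adjusted p of 0.0094 and Ly6d 0.101.

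**Figure D1:**
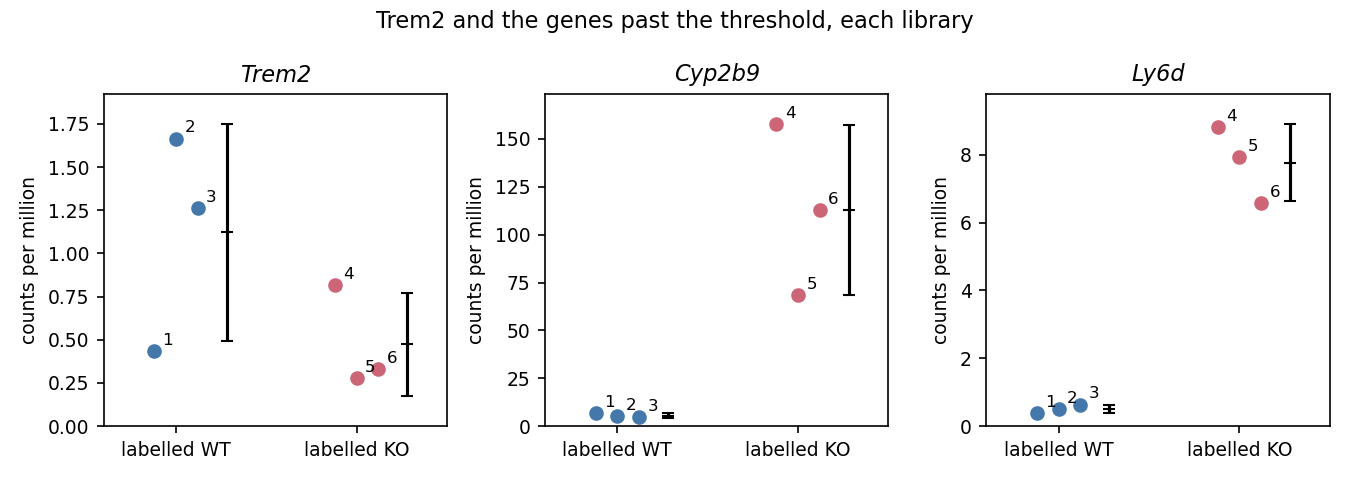
CPM of Trem2, Cyp2b9 and Ly6d in each library (points, numbered by replicate), with the mean and SD of the 3 libraries labelled WT and the 3 labelled KO. Cyp2b9 and Ly6d are apart between the groups, while Trem2 in WT replicate 1 (0.436 CPM) sits among the KO-labelled libraries.

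Gene lists fixed beforehand described the rest of the liver. Of 40 lists, 19 passed the set test against all other genes (camera with a preset correlation of 0.01, adjusted p under 0.05), 12 of them higher and 7 lower in the KO-labelled livers. With a correlation estimated from the data, 0 of the 40 lists passed, the lowest adjusted p being 0.171. For the 19 lists that value is given beside the count. Every other way of parting the 6 libraries 3 against 3 also passed lists at the preset correlation, between 6 and 22. A call at that setting therefore does not by itself mark the labelled groups. Fry's directional test passed 1 list, lipid droplets and lipid uptake (adjusted p = 0.0165), and its mixed test passed 9. Outside the lists holding Cyp2b9, no list had a member past the threshold over all genes. List members other than those taken by the fixed rule were chosen after their values were seen.

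Genes of fat storage were higher in the KO-labelled livers. Of 24 measured genes for lipid droplets and lipid uptake, 19 were fitted higher, with a median log2 change of 0.52 (camera adjusted p = 1.39e-06; adjusted p = 0.171 with an estimated correlation). Adjusted over the list alone, 8 members passed, all higher. Apoa4, an apolipoprotein of triglyceride-rich particles, stood at 201 ± 41.9 CPM in WT-labelled and 1070 ± 279 CPM in KO-labelled livers (log2 2.41, SE 0.30). Cidec, which enlarges lipid droplets, stood at 14.2 ± 8.41 and 93.3 ± 23.1 CPM (log2 2.72, SE 0.43). Cidea, of the same family, had a log2 change of 4.15 (SE 0.65), and Cd36, a fatty acid transporter, stood at 44.0 ± 14.0 and 140 ± 17.8 CPM (log2 1.67, SE 0.29). The change of Cidea rests on few reads, with 1, 5 and 7 counts in the WT-labelled libraries. The edgeR adjusted p over all genes of these 4 ranged from 0.156 to 0.297.

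PPARA targets and peroxisomal oxidation, the fat-burning programme of the fasting liver, were also higher. There 23 of 28 members were fitted higher, with a median of 0.48 (camera adjusted p = 1.68e-06; adjusted p = 0.377 with an estimated correlation), and 8 passed adjusted over the list alone. Pex11a, a peroxisome division factor, went from 136 ± 16.6 to 288 ± 66.5 CPM without passing over all genes (log2 1.09, SE 0.25), and Crat, carnitine acetyltransferase, had a log2 change of 1.41 (SE 0.36). With 1 library left out the median ranged from 0.33 (without KO replicate 6) to 0.73 (without WT replicate 1). The white adipose tissue list (7 of 8 fitted higher, median 0.55, camera adjusted p = 0.00451; adjusted p = 0.24 with an estimated correlation) passed as well, and adjusted over the list alone its members Cidea and Fabp4, a fatty acid carrier (log2 1.47, SE 0.39), were higher. Both also belong to the lipid droplet list, and with 1 surrogate variable in the model the adipose list had a median of 0.50 and an adjusted p of 0.0773.

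The sex-biased programme of the liver was shifted towards the female side. Of 26 male-biased liver genes 24 were fitted lower, with a median log2 change of −1.24 (camera adjusted p = 6.34e-12; adjusted p = 0.343 with an estimated correlation), and 13 passed as lower adjusted over the list alone. Hsd3b5, a male-predominant steroid dehydrogenase, stood at 186 ± 90.7 CPM in WT-labelled and 13.9 ± 10.6 CPM in KO-labelled livers (log2 −3.73, SE 0.61, edgeR adjusted p = 0.285). Cyp4a12b, a male-predominant fatty acid hydroxylase, stood at 57.6 ± 15.2 and 10.9 ± 2.59 CPM (log2 −2.40, SE 0.28, edgeR adjusted p = 0.155). Of 17 female-biased genes 12 were fitted higher, with a median of 0.78 (camera adjusted p = 7.45e-05; adjusted p = 0.343 with an estimated correlation), and 5 passed adjusted over the list alone. Besides Cyp2b9 these included Cyp2b13, with 58, 17 and 38 counts in the KO-labelled libraries against 1, 0 and 0 in the WT-labelled ones, and Acot3, which is also in the PPARA list. The female list has 31 members, of which only the 17 were tested. Genes such as Cyp2b13, near 0 in WT-labelled livers, pass the count filter only through the KO-labelled ones, which can raise the female median. Without WT replicate 1 the medians were −0.79 and 0.40. Major urinary protein genes in the male list are near-identical copies whose reads can be exchanged between them.

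Cell cycle genes and genes of stellate cells and fibrosis were higher as sets. Of 30 cell cycle genes 27 were fitted higher, with a median of 1.20 (camera adjusted p = 4.23e-12; adjusted p = 0.24 with an estimated correlation), and 12 passed adjusted over the list alone. Mki67, a marker of proliferating cells, stood at 2.07 ± 0.942 and 7.63 ± 1.91 CPM (log2 1.87, SE 0.42), and Ccnb1, cyclin B1, had a log2 change of 3.33 (SE 0.63). Ccnb1 had only 1, 1 and 3 counts in the WT-labelled libraries, against 9, 30 and 12 in the KO-labelled ones. Genes so near 0 in WT-labelled livers pass the count filter only through the KO-labelled ones, which can raise the cell cycle median. Of 21 genes of stellate cells and fibrosis 18 were fitted higher, with a median of 0.89 (camera adjusted p = 1.53e-07; adjusted p = 0.357 with an estimated correlation), and 10 passed adjusted over the list alone. Col3a1, a fibrillar collagen, stood at 21.9 ± 11.6 and 106 ± 51.4 CPM (log2 2.28, SE 0.51), and Vim, the mesenchymal filament vimentin, had a log2 change of 1.66 (SE 0.35). None of these 4 genes passed over all genes, at edgeR adjusted p from 0.319 to 0.37. Within the stellate cell list the change was uneven. Lrat, Reln, Colec11 and Dcn had log2 changes of −0.03, 0.15, −0.07 and −0.01, while Des and Pdgfrb had 1.92 and 0.66.

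Macrophage and endothelial markers were higher as sets. Kupffer cell genes, of the resident liver macrophages, had 14 of 17 members fitted higher (median 0.61, camera adjusted p = 0.000197; adjusted p = 0.24 with an estimated correlation), 5 of them passing adjusted over the list alone. Csf1r, the receptor that keeps macrophages alive, stood at 15.2 ± 2.57 and 28.2 ± 3.34 CPM (log2 0.89, SE 0.21), and Cd163, a haemoglobin scavenger receptor, had a log2 change of 1.35 (SE 0.33). All 14 measured genes of monocytes and inflammatory macrophages were fitted higher (median 0.71, camera adjusted p = 1.52e-05; adjusted p = 0.24 with an estimated correlation), as were all 16 of liver sinusoidal endothelium (median 0.40, camera adjusted p = 0.000107; adjusted p = 0.24 with an estimated correlation). In these lists Tyrobp, the adaptor through which the Trem2 protein signals, had a log2 change of 0.95 (SE 0.26), and Eng, the endothelial receptor endoglin, of 1.04 (SE 0.30). Lipid-associated macrophage genes, a programme known to depend on Trem2, had 13 of 18 members fitted higher (median 0.28, camera adjusted p = 0.0333; adjusted p = 0.284 with an estimated correlation). Their members adjusted over the list alone were Cd36, which hepatocytes also express, and Lgals3, galectin-3 (log2 1.64, SE 0.38). This list's call was lost without WT replicate 2 (median 0.39, adjusted p = 0.213) or KO replicate 5 (median 0.32, adjusted p = 0.146).

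Hepatocyte, complement and coagulation, and ribosomal protein genes were lower as sets. Hepatocyte core genes had 25 of 28 members fitted lower (median −0.50, camera adjusted p = 6.24e-06; adjusted p = 0.412 with an estimated correlation), and complement and coagulation genes 25 of 29 (median −0.44, camera adjusted p = 3.92e-06; adjusted p = 0.413 with an estimated correlation). F11, coagulation factor XI, stood at 97.6 ± 33.7 and 40.6 ± 7.46 CPM (log2 −1.27, SE 0.29). Cytosolic ribosomal protein genes had 38 of 50 members fitted lower (median −0.28, camera adjusted p = 2.82e-05; adjusted p = 0.284 with an estimated correlation), among them Rpl30 (log2 −0.92, SE 0.26). Over these 3 lists 0 members passed adjusted over the list alone. Without WT replicate 1 the medians of the first 2 lists were −0.24 and −0.28, and with 1 surrogate variable −0.16 and −0.21.

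Cholesterol, insulin-response and endoplasmic reticulum stress lists were lower in the KO-labelled livers, and the oxidative stress list was higher. Cholesterol synthesis and uptake had 21 of 24 members fitted lower (median −0.38, camera adjusted p = 0.00125; adjusted p = 0.474 with an estimated correlation). That call was lost without KO replicate 6 (median −0.30, adjusted p = 0.0802), and without KO replicate 5 the median was −0.60. Glucose and insulin response had 18 of 24 members fitted lower (median −0.27, camera adjusted p = 0.0424; adjusted p = 0.474 with an estimated correlation), and Onecut1, a hepatocyte transcription factor (log2 −2.08, SE 0.47), and Igfbp2, a carrier of insulin-like growth factors (log2 −1.60, SE 0.38), passed adjusted over the list alone. Its call was lost without WT replicate 1, KO replicate 4 or KO replicate 5, at medians of −0.05, −0.18 and −0.41 and adjusted p of 0.463, 0.0558 and 0.0813. Endoplasmic reticulum stress had 17 of 22 members fitted lower (median −0.67, camera adjusted p = 0.0239; adjusted p = 0.573 with an estimated correlation), with Xbp1, a transcription factor of the unfolded protein response, at −1.32 (SE 0.36). It was lost without WT replicate 1 (median −0.16, adjusted p = 0.465) or KO replicate 5 (median −0.90, adjusted p = 0.0559), and without WT replicate 2 its median was −1.04. NRF2 targets of oxidative stress had 14 of 23 members fitted higher (median 0.25, camera adjusted p = 0.0398; adjusted p = 0.357 with an estimated correlation), with Gsta1, a glutathione transferase, at 2.68 (SE 0.65). That call was lost without WT replicate 2, KO replicate 5 or KO replicate 6, at medians of 0.40, 0.37 and 0.18 and adjusted p of 0.327, 0.177 and 0.0643, and the median was 0.15 without WT replicate 1. With 1 surrogate variable the medians of the cholesterol, glucose and endoplasmic reticulum stress lists were −0.19, 0.01 and −0.02, none past the test. The oxidative stress list did pass in that fit, with a median of 0.17 (camera adjusted p = 0.00566; adjusted p = 0.348 with an estimated correlation).

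All 13 mitochondrially encoded respiratory chain genes were fitted higher in the KO-labelled livers. Their median was 0.79 (camera adjusted p = 0.00451; adjusted p = 0.592 with an estimated correlation), and mt-Nd4, a subunit of complex I, stood at 12700 ± 4121 CPM in WT-labelled and 28450 ± 16220 CPM in KO-labelled livers without passing over all genes (edgeR adjusted p = 0.613). Mitochondrially encoded genes took 8.16%, 12.7% and 10.2% of the counts of WT replicates 1, 2 and 3, and 28%, 9.08% and 19.8% of KO replicates 4, 5 and 6. Without KO replicate 4 the median was 0.31 (adjusted p = 0.227), and with the log2 mitochondrial share as a covariate, added after seeing the data, it was −0.09 (adjusted p = 0.368). That covariate holds these genes' own share, so the fit with it was bound to remove their change and decides nothing. The 74 nuclear-encoded genes of the respiratory chain had a median of 0.01 (camera adjusted p = 0.682), against a fitted mean of −0.05.

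**Figure D2:**
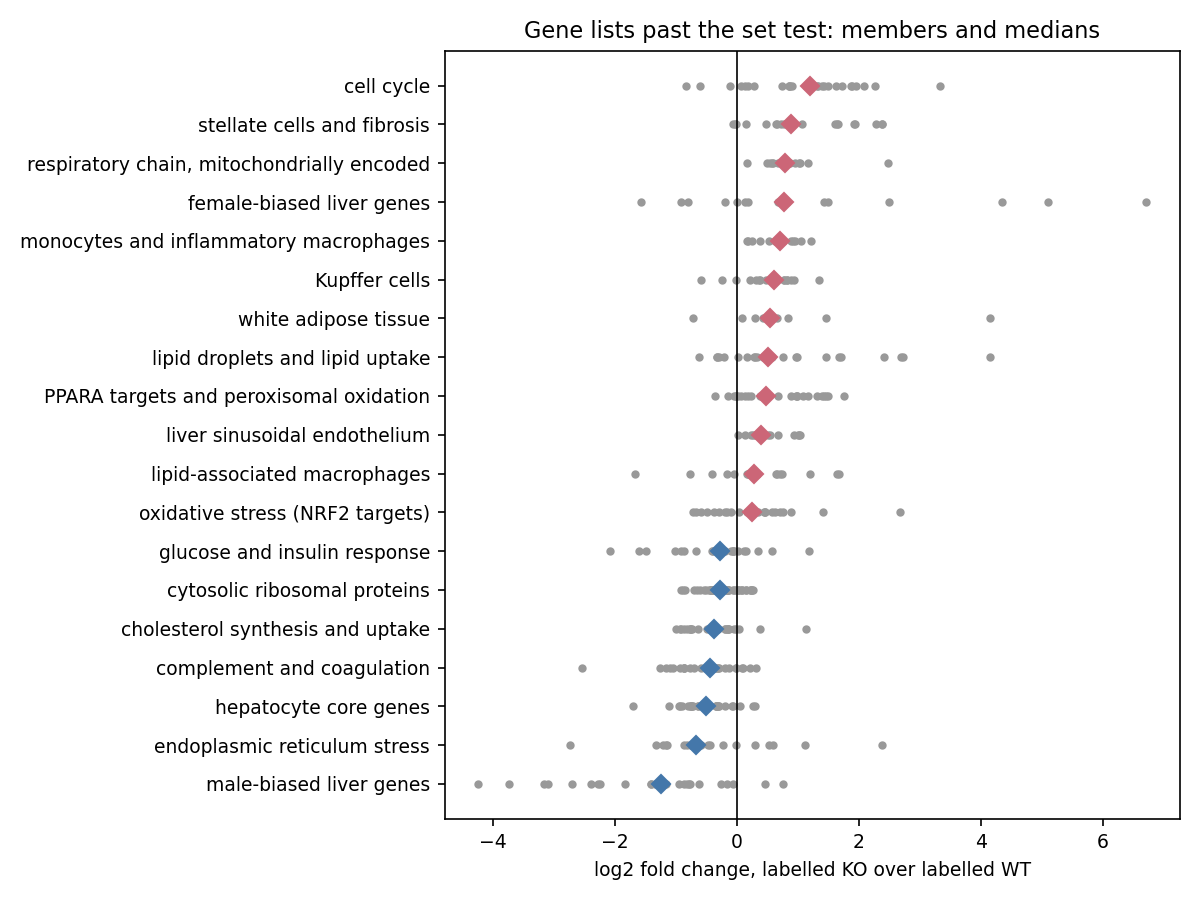
Log2 fold changes, labelled KO over labelled WT, of the measured members (grey) of the 19 lists past the set test, with each list's median (diamond; red higher, blue lower). The medians run from −1.24 for male-biased liver genes to 1.20 for cell cycle genes, and members spread widely around them.

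The other 21 lists did not pass. Among lists of fat synthesis and mitochondrial function, de novo lipogenesis had a median of 0.08 (camera adjusted p = 0.924), mitochondrial fatty acid oxidation −0.07 (0.566; 0.30 with 1 surrogate variable, adjusted p = 0.00377, or 0.678 with an estimated correlation), the TCA cycle and pyruvate dehydrogenase −0.20 (0.164) and mitochondrial biogenesis and dynamics −0.10 (0.0931). Inflammatory lists did not pass either, with cytokines and chemokines at 0.18 (0.258), interferon-stimulated genes at 0.27 (0.0931) and acute phase proteins at −0.45 (0.0931). Ifi27l2a, an interferon-induced gene (log2 1.70, SE 0.28), and Orm2, an acute phase glycoprotein (log2 1.31, SE 0.23), each passed adjusted over its list alone. Bile acid synthesis and transport had a median of −0.12 (0.173), the circadian clock −0.24 (0.0931), immediate early genes 0.02 (0.901) and the Trem gene cluster with its flanking genes 0.26 (0.17). Xenobiotic metabolism had a median of −0.18 and a mean of 0.26 (camera adjusted p = 0.744, direction up), with 6 higher and 2 lower members passing adjusted over the list alone, Cyp2b9 among the former.

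Markers of other cells and tissues gave medians of −0.49 for B cells and plasma cells (camera adjusted p = 0.0649), 0.55 for T and NK cells (0.566), −0.33 for neutrophils (0.515), 0.13 for dendritic cells (0.566), 0.17 for cholangiocytes (0.741) and −0.16 for erythroid cells (0.302). With 1 library left out, the medians ranged from −0.83 (without KO replicate 4) to 0.03 (without WT replicate 2) for B cells and plasma cells, and from 0.02 (without KO replicate 6) to 0.66 (without KO replicate 5) for T and NK cells. They ranged from −1.01 (without KO replicate 6) to 0.41 (without WT replicate 1) for neutrophils, and from −0.09 (without WT replicate 1) to 0.26 (without KO replicate 5) for dendritic cells. For cholangiocytes the range was 0.05 (without WT replicate 3) to 0.14 (without KO replicate 5), and for erythroid cells −0.69 (without KO replicate 5) to 0.06 (without KO replicate 4). Genes were filtered anew in each of these fits, so a list's measured members could differ. With all libraries, neutrophils were measured through 4 of 16 members, and T and NK cells through 7 of 20, with a mean change of 0.04. Cd4, a surface protein of helper T cells, was the T and NK cell member that passed as lower adjusted over the list alone (log2 −2.21, SE 0.59). Pancreatic acinar tissue and skeletal muscle were each measured through 1 gene, Cela1 (log2 −1.28, SE 0.45, list adjusted p = 0.135) and Mylpf (log2 2.42, SE 0.79, list adjusted p = 0.146). In KO replicate 5, Mylpf was at 7.46 CPM, against 0.512 to 1.25 CPM in the other libraries. Without that library the median of the skeletal muscle list was 0.95. The acinar list's median was −0.62, −0.59 and −0.64 without WT replicate 1, KO replicate 4 or KO replicate 6, and between −1.57 and −1.52 without another library. In these fits further list members could pass the count filter, so these medians need not be the changes of Mylpf and Cela1.

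Several of these outcomes changed with the library left out, since 9 of the 21 lists passed in such a fit. B cells and plasma cells passed as lower without WT replicate 1, KO replicate 4 or KO replicate 6, at adjusted p of 0.000108, 0.00278 and 0.0263. Acute phase proteins passed as lower without WT replicate 2 (0.00112) or KO replicate 6 (0.0225), the TCA cycle without WT replicate 2 (0.0053) or KO replicate 5 (0.0397), and the circadian clock without WT replicate 1 (0.0418) or KO replicate 4 (0.018). Mitochondrial fatty acid oxidation passed as lower without WT replicate 2 (0.0356), and bile acid genes without KO replicate 6 (0.0203). Interferon-stimulated genes passed as higher without WT replicate 3 (0.0202) or KO replicate 5 (0.0132), immediate early genes without KO replicate 5 (0.0458), and skeletal muscle without KO replicate 4 (0.0499). Medians also shrank or changed sign: without WT replicate 1 they were −0.03 for acute phase proteins, −0.01 for the TCA cycle, 0.21 for mitochondrial fatty acid oxidation and 0.16 for xenobiotic metabolism. Without KO replicate 6 the interferon median was 0.08, and without KO replicate 4 that of immediate early genes was −0.60. Others grew: the TCA cycle median was −0.42 without WT replicate 2 and −0.49 without KO replicate 5. That of xenobiotic metabolism was −0.42 without WT replicate 2, and the interferon median was 0.44 without KO replicate 5. With 1 library left out, de novo lipogenesis ranged from −0.08 to 0.28, cytokines and chemokines from 0.05 to 0.39, the circadian clock from −0.38 to −0.13, bile acid genes from −0.44 to −0.09, mitochondrial biogenesis and dynamics from −0.18 to −0.10 and the Trem gene cluster from 0.11 to 0.43.

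Genes near Trem2 on chromosome 17 were examined because DNA around a targeted gene can differ between genotypes. Of 143 genes tested within 10 Mb, 0 passed the threshold in edgeR, against 2 of 13549 elsewhere (Fisher's exact test, two-sided, p = 1). DESeq2, with 165 calls among 15230 genes in all, called 5 there. At an unadjusted p under 0.05 in edgeR there were 23 genes within 10 Mb, 16.1% against 8.5% elsewhere (Fisher's exact test, two-sided, p = 0.0037). The test treats genes as independent, which neighbours need not be. The smallest p values near Trem2, named after they were seen, belonged to Adgrf1, Pla2g7 and Lrrc73. Adgrf1, an adhesion G protein-coupled receptor, had 47, 22 and 86 counts in WT-labelled and 0, 1 and 1 in KO-labelled libraries. Pla2g7, a phospholipase that circulates with lipoproteins, had 29, 19 and 42 against 94, 133 and 142 counts, and Lrrc73 had 3, 1 and 2 against 13, 22 and 25.

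The libraries differed from each other in ways that the labels do not fully explain. The first principal component held 57.1% of the variance and did not fully separate the groups, with scores of −79.8, 24.2 and −29.7 for WT replicates 1, 2 and 3 and 63.3, −22.6 and 44.5 for KO replicates 4, 5 and 6. Only WT replicate 2 and KO replicate 5 break its alignment with the labels, so the group comparison is partly confounded with it. Without them, 2012 and 2662 genes had an unadjusted edgeR p under 0.05. The surrogate variable had the same signs in all libraries. Across genes, WT replicate 3 and KO replicate 5 had a Spearman correlation of 0.974, as high as WT replicates 1 and 3, while WT replicates 1 and 2 reached 0.928. The highest correlation was within a group (KO replicates 4 and 6, 0.978) and the lowest between groups (WT replicate 1 and KO replicate 4, 0.895).

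**Figure D3:**
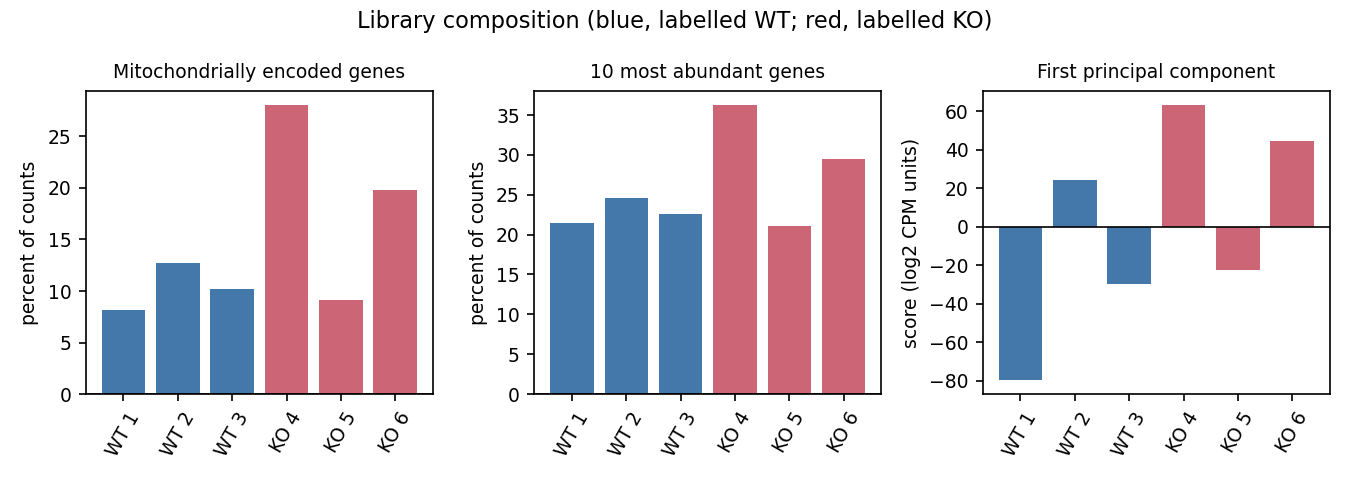
Share of counts from mitochondrially encoded genes, share of the 10 most abundant genes, and score on the first principal component of log2 CPM for each library (blue, labelled WT; red, labelled KO). KO replicates 4 and 6 have the highest mitochondrial shares, 28% and 19.8%, and the component's sign follows the labels only in part.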

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

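The surrogate variable, the mitochondrial covariate, robust dispersions and the 2 libraries left out together were chosen after seeing the data; the other settings were planned. Genes higher and lower in KO numbered 2 and 0 in edgeR, but 105 and 60 in DESeq2, 2070 and 1993 in limma-voom with sample quality weights, 39 and 22 without the low-count filter, and 6 and 4 with 1 surrogate variable. There was 1 higher gene in limma-voom, with library size alone and with the mitochondrial covariate, 0 with the 2 libraries left out or at an adjusted p under 0.01, and there were 2 lower genes with FPKM plus 0.1. Leaving out 1 library gave between 0 and 1 higher and 0 lower genes. DESeq2 shared both edgeR calls and had 5 calls near Trem2 in place of 0. The Trem2 difference passed in 1 setting, limma-voom with sample quality weights (log2 −1.53, adjusted p = 0.0445), and without 1 library ranged from −1.87 to −0.92. Lists past the set test went from 19 to 0 with an estimated correlation and lay between 17 and 22 in the other settings, 18 to 20 with 1 library left out; 12 of the 19 passed in all of these except the estimated correlation. Lists that had not passed and passed in the other direction, at the preset correlation, were dendritic cells (median −0.23 with the 2 libraries left out), mitochondrial fatty acid oxidation (0.30 with the surrogate variable, adjusted p = 0.678 with an estimated correlation, 0.33 with the covariate, 0.41 with the 2 libraries left out) and the TCA cycle (0.14 with the covariate), and xenobiotic metabolism, whose mean was above 0, passed as higher with the 2 libraries left out (median 0.19); the medians of 9 lists that had not passed changed sign without 1 library; the mitochondrially encoded list turned to −0.09 with the covariate, which holds those genes' own share. The cause of the other changes was not tested. Of single named genes, 1477 comparisons with the alternatives kept direction and side of the threshold, 105 passed where they had not, 16 lost the call and 7 moved. Only Cyp2b9 and Ly6d had a call to lose, so all 16 losses fell on them. Most of the 1477 were genes that stayed uncalled, and the count does not measure how stable the calls were. In simulation 6% of 2-fold and 56% of 4-fold changes were recovered, so 2-fold changes are mostly out of reach of 3 libraries per group.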

Other observations

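Of the tests in this part, the Xist, mislabelling, macrophage, GC and list-split tests were set before their results were seen, and the others after; the genes of the first paragraph were chosen after their values were seen. Outside the lists, several single genes passed in DESeq2 but not in edgeR. Lifr, the receptor of leukaemia inhibitory factor, stood at 253 ± 39.8 CPM in WT-labelled and 78.1 ± 7.93 CPM in KO-labelled livers (log2 −1.70, SE 0.22, edgeR adjusted p = 0.165). It passed in DESeq2 (adjusted p = 3.45e-08) and with 1 surrogate variable (adjusted p = 0.0419). Foxq1, a forkhead transcription factor, stood at 59.8 ± 17.1 and 13.9 ± 7.16 CPM (edgeR adjusted p = 0.355). Fitted higher were Anxa2, a membrane-binding annexin (log2 1.89, SE 0.27), its partner S100a10 (log2 1.00, SE 0.21), the actin-capping Capg (log2 1.85, SE 0.33), the tubulin gene Tubb2a (log2 2.55, SE 0.51) and Ucp2, a mitochondrial carrier, at 24.4 ± 4.54 and 65.3 ± 2.51 CPM. All of these were among the 165 DESeq2 calls, 160 of which had an unadjusted p under 0.05 in edgeR.

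The B cell and plasma cell list did not pass, but did so in settings that handle doubted libraries differently. Its median of −0.49 (camera adjusted p = 0.0649) became −0.92 with 1 surrogate variable (adjusted p = 4.28e-05), −0.96 with the mitochondrial covariate (adjusted p = 8.01e-06) and −1.24 without WT replicate 1 and KO replicate 4 (adjusted p = 4.47e-07). These calls rest on the preset correlation: with an estimated one the adjusted p was 0.629, and 0.431 with the surrogate variable. Without WT replicate 2 the median was 0.03 (adjusted p = 0.343). Igha, the constant region of immunoglobulin A, stood at 14.9 ± 8.19 and 7.88 ± 1.99 CPM, and Iglc2, a light chain constant region, at 1.44 ± 0.589 and 0.657 ± 0.252 CPM.

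The first pattern is the fall of male-biased with the rise of female-biased liver genes. A female mouse among the KO-labelled livers is argued against by Xist, whose highest value there was 0.131 CPM, with the Y-linked Ddx3y at 36.4 CPM or more. A smaller share of hepatocytes would lower female-biased genes too, yet their median was 0.78 with a lower quartile of 0.00, above the upper quartile of −0.30 of the hepatocyte core genes. This argues only weakly, since female-biased genes near 0 in WT-labelled livers are measured only where KO-labelled counts are high. The library structure held by the surrogate variable is argued against as the whole cause by a male-biased median of −0.80 with that variable (camera adjusted p = 1.26e-09), but only weakly, since with an estimated correlation the adjusted p was 0.348. As a hypothesis, the genotype as labelled may alter the sex-dependent programme of hepatocytes; body weight, hormones and chance remain open and untested.

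The second pattern is the low Trem2 count in the library labelled WT replicate 1. Chance stays open: counting error alone gives p = 0.00102 for 7 counts against 52 in the other WT-labelled libraries together (two-sided exact conditional test), but with the spread between libraries and times 3, as this library was picked for its count, p = 0.485 (negative binomial exact test). A KO liver under a WT label is argued against, but only weakly, by the 50 genes that best part the groups without it: its median position was −0.03 on a scale where the WT mean is 0 and the KO mean is 1, with quartiles of −0.37 and 0.27. The fit without this library called 0 genes, so these 50 are not established differences. WT replicate 1 also has the lowest score on the first principal component (−79.8). Genes following that component would keep it from the KO mean whatever its genotype. Fewer macrophages overall would lower their other genes by a like amount, but 35 genes of Kupffer cells and lipid-associated macrophages differed by a median of −0.20 (quartiles −0.63 and 0.16) where Trem2 differed by −1.50 on the log2 scale. A lower number of the macrophages that carry Trem2 alone stays open, and no biological explanation was tested, since the labels set this library apart only by a suffix of unknown meaning.

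The third pattern is a structure of the libraries: parting replicates 1, 3 and 5 from 2, 4 and 6 called 2443 genes, where the labelled groups gave 2, and replicates 2, 4 and 6 also had higher mitochondrial shares (12.7%, 28% and 19.8%, against 8.16%, 10.2% and 9.08%). The signs of the first principal component and of the surrogate variable part the libraries in the same way, so these are not separate structures. A few abundant genes taking the counts would lower the others together, yet with library size alone 42.9% of 1402 other called genes were higher in 2, 4 and 6; scaling without the abundant genes, set beforehand, decides nothing, since it moved library sizes by factors of only 0.983 to 1.02. GC content and gene length stay open as parts, with Spearman correlations across called genes, which are not independent, of 0.11 and 0.19 with the log2 difference. Non-coding RNA stays open too. Of the genes higher in 2, 4 and 6, 15.4% were not annotated as protein-coding, against 8.66% of those lower (Fisher's exact test, p = 4.44e-07), short of the doubling set as its mark. This class also takes in pseudogenes and immunoglobulin genes, and the test treats genes as independent. Non-coding gene types without pseudogenes took 0.784%, 0.643% and 0.67% of the counts of replicates 2, 4 and 6, against 0.382%, 0.539% and 0.501% of 1, 3 and 5. RNA quality was not measured and stays open, and no biological explanation was tested, since the labels put these libraries in no common group.

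The 6 libraries allow 10 splits, too few for a share under 0.05. In 2 of the 10 splits, the real one included, as many genes were called as the real 2, the highest other split being that with 2443, and in the same 2 as many genes reached an unadjusted p under 0.05 (1175 in the real split, 4786 in the highest other). In 3 of the 10 splits as many lists passed the set test as the real 19, the highest other split giving 22. Every other split also had lists past the test, the fewest being 6. Passing at the preset correlation therefore does not by itself mark the labelled groups.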
